A study of Arabidopsis thaliana with 4 samples.

How the data were processed

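Genomic DNA of 12-d-old whole seedlings grown on agar under 16 h of light and 8 h of dark was analysed by bisulfite sequencing, with 1 library for each of Col wild type, csn5a-1, Ws wild type and csn8. Per the labels' protocols, adapters were methylated, libraries passed through bisulfite conversion in succession with a commercial kit, and they were then amplified by PCR and sequenced. The labels' protocol text also speaks of RNA extraction and of honey bee stages, and the design text of histone modifications, so parts of it belong to other work. The submitters' processing notes name Bowtie, without a version, and the genome build TAIR10. The caller of methylation, the coverage filter and the treatment of duplicate reads are not given in the sources used here.

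The deposited table gave, per the file headers, a chromosome, position, sequence context and a methylation level per library, as a fraction from 0 to 1. It holds neither reads nor coverage, so the depth per sample and per site is unknown and no counting interval or detection limit could be given. A level from few reads takes few values, and the share of cytosines at 100% differed between libraries. In CG it was 15.8% in Col, 29.8% in csn5a-1, 14.8% in Ws and 32.9% in csn8, and in CHG 3.75%, 4.82%, 2.41% and 13.5% in the same order. Shares at 0 were 34.7%, 33.6%, 32.9% and 39.1% in CG and 42.4%, 39.5%, 36.7% and 40.2% in CHG. In CHH they were 53.0%, 61.5%, 47.8% and 69.2%, and the CHH median was above 0 only in the library labelled Ws. The library labelled csn8 exceeded that labelled Ws both at 0 and at 100% in every context (CHH at 100%: 0.518% against 0.0992%). Whether depth or methylation sets these shares was not tested. Every row had a value in all 4 libraries and at least 1 above 0; none was at 0 in all. The authors' column with the highest level of each row was not used. Zeros behaved as measurements: where the minus-strand cytosine of a CG pair was above 80%, its partner was at 0 in 0.160% of pairs in Col, 0.0386% in csn5a-1, 0.0322% in Ws and 0.252% in csn8. Levels on the strands of 143900 pairs correlated at 0.886, 0.936, 0.921 and 0.903 in these libraries.

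Fractions were turned to percent and averaged without weights over listed cytosines, per context, and differences are in percentage points. The SD over the 5 chromosomes describes unevenness along the genome, not replicate error. Gene levels are means over listed cytosines between the annotated start and end of 37887 nuclear genes of all biotypes, with at least 5 listed cytosines of the context; overlapping genes share cytosines. Gene borders and names came from a RefSeq table of the assembly TAIR10.1, matched on locus tag, whose coordinates are not printed; positions in the text are the first and last listed cytosines of a gene. As a check that the borders suit the deposited positions, mean CG level was taken in bins of 100 bp around gene ends for each of the 5 chromosomes. The lowest bin lay within 200 bp of the border in both groups of genes of each chromosome, the first and the last by position, at 8.88% to 21.0%, against at least 31.0% at 900 to 1000 bp outside. The table has no strand, exons or introns, so position within a gene is not described. All 112 loci of the gene lists were found.

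Before the data were examined, a size rule was fixed of at least 20 points in CG, 10 in CHG and 5 in CHH. With 1 library per group there are no replicates, and no p-value is given. A planned minimum of 20 reads per gene could not be applied to levels without reads. Measurement error of CG differences was described by estimating each gene's difference separately from the cytosines of each strand, in genes with at least 3 pairs. There were 9 gene lists with 112 loci, 2 of them in more than 1 list: COP9 signalosome subunits, DNA methylation and demethylation, methyl donor supply, known methylation-sensitive loci, PAI and HISN6 ecotype epialleles, light signalling, cullin-RING ligases and neddylation, auxin, and photosynthesis and pigment. The median difference of each list was placed among 10000 random lists of the same size matched on deciles of level, as a description of these libraries. Levels were simulated for csn5a-1 against Col in CG with 16054 genes, as 10 independent reads per cytosine around a mean common to all libraries. Only genes of intermediate level were shifted. The size rule was passed by 98% of 100 genes raised by 40 points, 79% of 100 lowered by 30 points and 0.0569% of 15806 unchanged genes. Real depth is unknown and variation between plants was not simulated, so these shares are not error rates for the real libraries.

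Genes named in the text were chosen by rule: for each mutant comparison the 8 largest CG gains and losses and the 3 largest in CHG and in CHH, the 5 largest shared gains and losses in CG ranked by the smaller difference, the 5 largest gains and losses in CG between the wild types, list genes past the size rule in a mutant comparison, and CSN5A, CSN8 and the PAI and HISN6 genes. Of the list genes past the rule, examples are given and the rest counted. The classes by biotype, the agreement of CG states between libraries and the dense block on chromosome 2 were added after seeing the data. The block is the longest run of 10 kb windows with at least 1500 listed cytosines.

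Alternatives tried were the median in place of the mean, a minimum of 10 or 1 cytosines per gene, size rules of other sizes, centring on the median difference and the mean of a list. Alternatives chosen after seeing the data left out the chromosome 2 block, exchanged the wild types, or took CHG cytosines above 0 in both Col and csn5a-1, the last set before its own value was seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.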

Results

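Whole-genome bisulfite sequencing measured DNA methylation at single cytosines in 12-d-old light-grown Arabidopsis thaliana seedlings. Bisulfite converts unmethylated cytosine and leaves 5-methylcytosine, so the share of unconverted reads at a position is its methylation level. There were 4 libraries: wild type of the ecotype Columbia (Col), the csn5a-1 mutant described as non-lethal and in Col, wild type of the ecotype Wassilewskija (Ws), and the lethal csn8 mutant described as in Ws. CSN5A and CSN8 encode subunits of the COP9 signalosome, a complex that removes the ubiquitin-like protein NEDD8/RUB from cullins and was found through mutants that develop in darkness as if in light. Each group had 1 library, so there was no replicate spread and no test across replicates. The design compares each mutant with the wild type of its ecotype, the wild types with each other, and the mutants with each other. The deposited table held 361196 cytosines in CG, 454510 in CHG and 1638751 in CHH (H is A, C or T), each with a level in all 4 libraries and above 0 in at least 1. The read depth behind each level is unknown, so no counting interval is given.

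The targeted genes did not check the genotypes, because a mutation need not alter methylation of its own gene. CSN5A (AT1G22920, chromosome 1) had a CHG level of 14.6% over 9 listed cytosines in the library labelled csn5a-1, against 1.23% in the library labelled Col, 0.926% in that labelled Ws and 2.22% in that labelled csn8. Its CHH level over 18 cytosines was 7.97% in the library labelled csn5a-1 and 2.22% in the library labelled Col. Of the 9 CHG positions, 7 were above 0 in the library labelled csn5a-1, between 8111097 and 8111969, and all 7 were at 0 in the libraries labelled Col and Ws. CSN8 (AT4G14110, chromosome 4) had 4 listed CG cytosines, under the minimum of 5, and its CHH level over 12 cytosines was 4.86% in the library labelled csn8, 1.69% in that labelled Ws, 4.05% in that labelled Col and 5% in that labelled csn5a-1.

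Loci with known ecotype differences went against the label of a wild type. The PAI genes encode phosphoribosylanthranilate isomerase of tryptophan synthesis and are known to be densely methylated in Ws and not in Columbia. Over PAI1, PAI2 and PAI3 the mean CHG level was 72.0% in the library labelled csn8, 0.447% in that labelled Ws, 0.451% in that labelled csn5a-1 and 2.61% in that labelled Col. Mean CHH levels of the 3 genes were 29.6% in the library labelled csn8 and 0.304% in the library labelled Ws. HISN6A and HISN6B, a near-identical pair encoding histidinol-phosphate aminotransferase, had the opposite arrangement. HISN6B (AT1G71920) had a CHG level of 44.0% in the library labelled Col, 30.5% in the library labelled csn5a-1, 36.6% in the library labelled Ws and 0.578% in the library labelled csn8 over 68 cytosines. HISN6A (AT5G10330) had 41.0%, 26.9%, 24.9% and 0.667% in the same order over 75 cytosines. Reads of such gene copies can be placed on the wrong copy, so the copies are not 5 independent values.

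**Figure D1:**
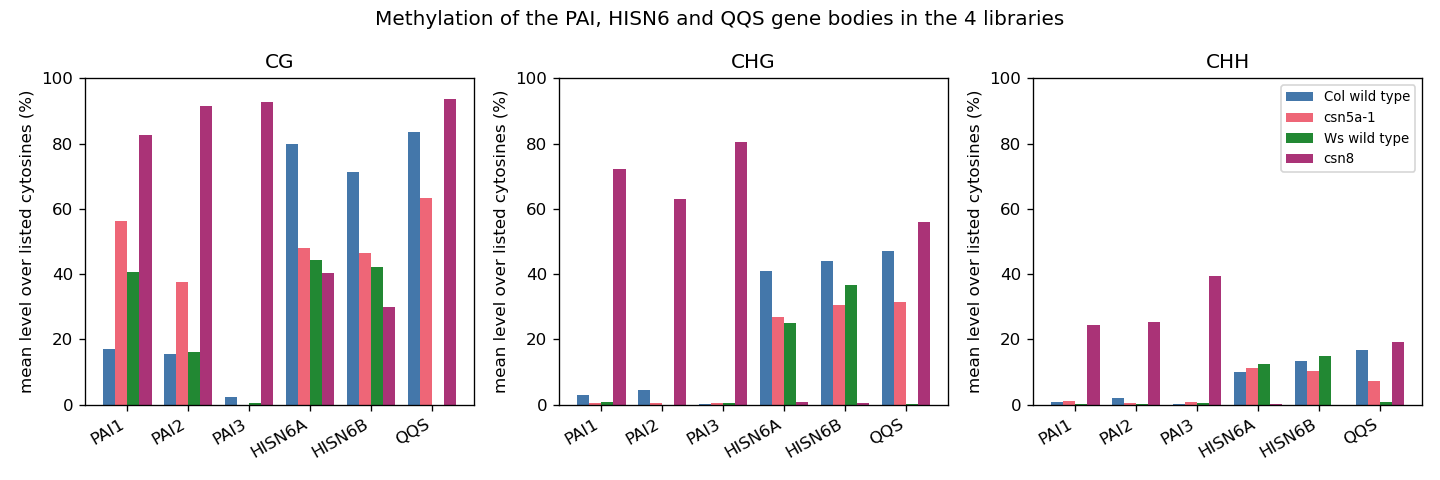
Mean methylation level in percent (vertical axis) over listed cytosines of the PAI1, PAI2, PAI3, HISN6A, HISN6B and QQS gene bodies (horizontal axis) in CG, CHG and CHH, 1 bar per library. PAI CHG levels stood at 72.2%, 63.1% and 80.6% in the library labelled csn8 and at 4.56% or less in the other libraries, while CHG at both HISN6 genes was under 1% in the library labelled csn8 alone.

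Gene-body CG methylation, which is copied through cell division and differs between lines, paired the libraries in another way than the labels. Across 16054 genes the Pearson correlation of CG levels was 0.916 between the libraries labelled csn5a-1 and Ws (Spearman 0.900). It was 0.731 between csn5a-1 and Col, 0.697 between csn8 and Ws, 0.728 between csn8 and Col, 0.751 between Ws and Col and 0.675 between csn5a-1 and csn8. These correlations are across genes, which are not independent replicates. At 116999 CG cytosines every library was either above 70% or at 0, and the libraries labelled csn5a-1 and Ws differed at 6.67% of them. Every other pair differed at 20.2% to 25.6%. Of the 24423 such cytosines that differed between the libraries labelled csn5a-1 and Col, 82.4% had the state of the library labelled Ws. Of the 29448 that differed between csn8 and Ws, 44.5% had the state of the library labelled Col. Because of this and the PAI levels, groups are called libraries labelled by their names, and no direction below is assigned to a mutation.

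**Figure D2:**
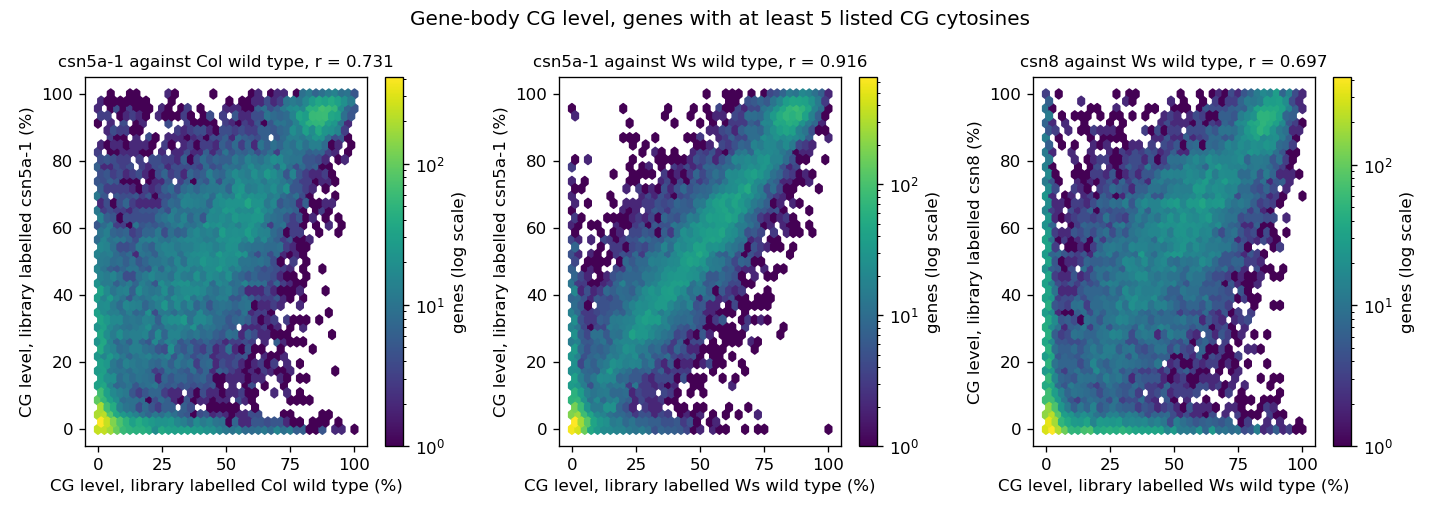
Gene-body CG level in percent for genes with at least 5 listed CG cytosines, as the number of genes per hexagon on a log colour scale, for 3 pairs of libraries. The libraries labelled csn5a-1 and Ws lie along the diagonal (r = 0.916), while csn5a-1 against Col (r = 0.731) and csn8 against Ws (r = 0.697) have many genes near 0 in 1 library and high in the other.

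Over all listed cytosines the mean CG level was 41.3% ± 3.49 in the library labelled Col, 48.4% ± 4.02 in that labelled csn5a-1, 43.7% ± 2.77 in that labelled Ws and 47.7% ± 4.09 in that labelled csn8, where each error is the SD over 5 chromosomes. Mean CHG levels were 26.1% ± 2.23, 27.5% ± 1.95, 24.9% ± 1.99 and 35.4% ± 2.60 in the same order. For CHH they were 10.1% ± 0.494, 8.88% ± 0.287, 9.40% ± 0.362 and 8.91% ± 0.258. Cytosines at 0 in all 4 libraries are not in the table, so these means exceed genome-wide levels in every library by a common factor if the unlisted cytosines were covered and unmethylated.

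A stretch of 270 kb on chromosome 2 (3240000 to 3509765), in the part of the chromosome known to hold an insertion of mitochondrial DNA, had 80929 listed cytosines, 3.30% of all. Its mean CG level was 12.1% in the library labelled Ws, 5.59% in the library labelled csn5a-1, 0.527% in the library labelled Col and 0.244% in the library labelled csn8. Mean CHG levels were 7.65%, 3.35%, 0.428% and 0.196%, and mean CHH levels 2.58%, 1.15%, 0.374% and 0.271%, in the same order.

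**Figure D3:**
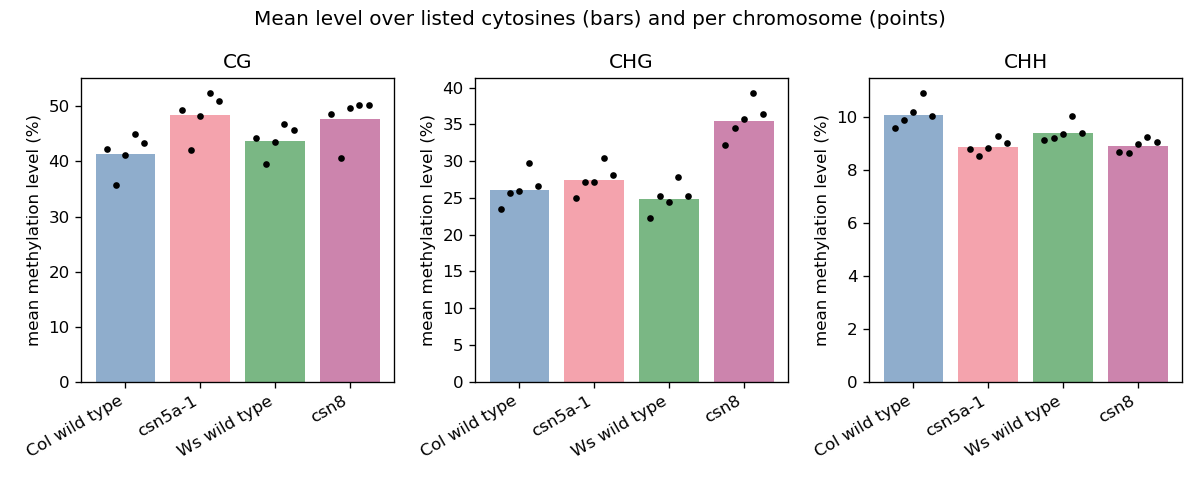
Mean methylation level in percent over listed CG, CHG and CHH cytosines (bars) and in each of the 5 chromosomes (points, chromosomes 1 to 5 from left to right) in the 4 libraries. Mean CHG in the library labelled csn8 was 35.4%, and its lowest chromosome, at 32.2%, lay above the highest chromosome of the other libraries, 30.4% in csn5a-1.

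The question of the first comparison is how methylation of csn5a-1 seedlings differs from that of Col wild type. The library labelled csn5a-1 had higher CG methylation than the library labelled Col in every class of gene examined. In protein-coding genes the mean CG level was 37.9% against 30.9%, and in pseudogenes, many of which are transposon remnants, 86.2% against 79.8%. CHH methylation of pseudogenes was lower, at 13.5% against 16.7%. At their listed CG cytosines, the single genes with the largest gaps were highly methylated in 1 library and near 0 in the other, a form that ranking by gap favours. Cytosines at 0 in all 4 libraries are not listed, so such a level can describe a short part of a gene. The listed CG cytosines of SDG40, for example, lay between 5668412 and 5668442. The genome-wide CG difference was 7.10 points ± 0.549 (SD over 5 chromosomes), with all 5 chromosomes and 120 of 121 windows of 1 Mb on the same side. The CHG difference was 1.35 points ± 0.355 and the CHH difference -1.20 points ± 0.321. Between medians over cytosines the differences were 25 points in CG, 2.5 in CHG and 0 in CHH.

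Of 16054 genes measured in CG, 3630 were at least 20 points higher in the library labelled csn5a-1 and 1355 at least 20 points lower. Centred on the median gene difference of 5.07 points, 2779 were higher and 1838 lower. In CHG, 1323 of 17692 genes were at least 10 points higher and 929 at least 10 points lower. In CHH, 2151 of 29946 were at least 5 points higher and 3219 at least 5 points lower. Estimated separately from each strand of the same CG pairs in 12283 genes, the CG differences had an SD of error of 5.86 points and correlated at 0.906. The sign was the same on both strands in 4857 of 4861 genes past 20 points. These genes were picked for a large difference in the same CG data, which favours agreement of sign. Strands of the same library also carry no variation between plants.

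Among the highest CG gains, AT3G05415, a pseudogene on chromosome 3 with listed CG from 1555651 to 1559090, stood at 98.8% in the library labelled csn5a-1 and 0.595% in the library labelled Col, a difference of 98.2 points ± 4.44 (SD over 12 cytosines). The protein-coding AT5G06043 (chromosome 5, 1817184 to 1817335) stood at 98.6% against 1.94%, and AT3G49230 (chromosome 3, 18254996 to 18255272) at 94.6% against 0.313% over 20 cytosines. The pseudogene AT2G12470 had 94.3% against 0% over 34 cytosines, and the pseudogene AT4G15590 had 97.7% against 4.17%. SDG40 (AT5G17240), named for a SET domain, had 93.6% against 1.67% over 6 cytosines. AT5G28462 and AT5G41430 completed the list at 98.8% and 93.9% in the library labelled csn5a-1. All 8 were above 45% in the library labelled Ws as well, from 47.0% at AT5G41430 to 100% at AT5G06043.

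The largest CG losses had the same arrangement. AT1G42490, a transcribed pseudogene on chromosome 1 with listed CG from 15946080 to 15946489, was at 0% in the library labelled csn5a-1 and 100% in the library labelled Col over 6 cytosines. The non-coding RNA genes AT2G06225 and AT1G08773 were at 0% against 95.8% and 91.7%. The pseudogene AT1G27285 was at 0.446% against 88.7% over 32 cytosines (chromosome 1, 9477798 to 9480424), and AT3G43690 at 0.926% against 92.4%. AT2G04490, AT2G02650 and AT3G52510 had 94.4%, 94.0% and 87.8% in the library labelled Col and at most 2.5% in the library labelled csn5a-1. In the library labelled Ws all 8 were at or below 2.83%.

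In CHG the largest gains were at SADHU6-1, a pseudogene of the SADHU retroelement family on chromosome 3 (525430 to 525758), with 97.2% against 15.6% over 9 cytosines, at the pseudogene AT3G62475 with 81.1% against 3.81%, and at AT5G00720 with 81.8% against 1.83%. The largest CHG losses were AT3G43315 (2.93% against 72.0%), AT1G62915 (0% against 63.1% over 32 cytosines) and AT1G06577 (0% against 61.9%). In CHH, AT4G06800 and AT1G61685 were at 34.8% and 32.1% in the library labelled csn5a-1 and at 0% in the library labelled Col, and MIR4245, a microRNA gene, at 50.7% against 16.0%. AT1G05503, AT3G06295 and AT2G00800 had the largest CHH losses, from 66.7%, 60.7% and 55.1% in the library labelled Col to 0%, 5.19% and 0.741%.

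Members of the fixed gene lists differed one by one. Of 5 measured COP9 signalosome genes, 4 were at least 20 points higher in CG in the library labelled csn5a-1 and none lower. They were CSN1 (33.5% against 8.52%), CSN2 (29.1% against 0%), CSN3 (37.1% against 1.54%) and CSN4 (45.1% against 24.6%). These levels rest on 17, 7, 5 and 11 listed CG cytosines. The SD of the difference over cytosines was 54.0, 45.7, 52.4 and 42.0 points, so the gaps were uneven within each gene. The median of the list was 25 points, at percentile 93.2 of 10000 random lists matched on level (99.7 for 10 members with no minimum of cytosines). The library labelled Ws had CSN1 to CSN4 at 32.9%, 24.0%, 24.9% and 49.1%, and against it the list's median was 0.614 points at percentile 26.8. Among 24 genes of DNA methylation and demethylation, 5 were higher and 1 lower in CG. Among the 5 were the glycosylase gene DML2 (58.2% against 0.758%), AGO4 (80.3% against 41.0%) and the methyltransferase gene CMT2 (47.7% against 13.7%), and IBM1, a histone demethylase gene, was lower (30.2% against 52.3%). In methyl donor supply, 3 of 10 genes were higher and 1 lower, with the methionine synthase gene MS1 at 62.0% against 0.231% and the adenosine kinase gene ADK1 at 0% against 38.1%.

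Of the known methylation-sensitive loci, none of 8 was higher and 4 were lower in CG. These were SDC (1.59% against 23.4%), FIS2 (3.57% against 27.7%), IBM1 and QQS (63.2% against 83.6%). The list's median of -12.1 points lay at percentile 0.43 of random lists. It was -3.76 points at percentile 6.16 over the 5 members with at least 10 cytosines. With no minimum it was -3.43 points at percentile 4.15 over 10 members. Against the library labelled Ws in place of Col, the list's median was 1.68 points at percentile 54.5. Ws minus Col gave -13.8 points at percentile 0.61. In light signalling 2 of 8 were higher, PHYB (72.3% against 48.4%) and PIF3 (28.1% against 1.32%), and PHYA was lower (42.7% against 70.5%). Among 11 cullin-RING ligase and neddylation genes 1 was higher, ECR1 (33.5% against 1.25%), and 1 lower, COI1 (27.3% against 48.0%). None of 7 auxin genes passed 20 points, and of 4 photosynthesis and pigment genes LHCB1.1 did (25% against 1.39%). Median CG differences of these lists were 3.88 points in light signalling, 7.74 in neddylation, 0.874 in auxin and 11.7 in photosynthesis, at percentiles 21.6, 48.5, 40.2 and 76.9. For DNA methylation and methyl donor supply they were 8.98 and 6.43 points, at percentiles 74.6 and 59.4. PAI1 and PAI2 were higher and both HISN6 genes lower in CG, with a list median of -2.34 points at percentile 11.8. The library labelled csn5a-1 shared its CG pattern with that labelled Ws, so these directions are between libraries. They can be neither assigned to the mutation nor denied to it. Against the library labelled Ws in place of Col, 1921 genes passed the CG rule (1443 higher and 478 lower) and the genome-wide CG difference was 4.62 points.

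The second comparison asks how methylation of csn8 seedlings differs from that of Ws wild type. The library labelled csn8 had higher CHG methylation than the library labelled Ws at most pseudogenes and in nearly every part of the genome. Pseudogenes had a mean CHG level of 63.8% against 47.3%, with 2124 of 2756 at least 10 points higher and 79 at least 10 points lower. Protein-coding genes had 9.88% against 5.64%. CHH methylation of pseudogenes was lower, at 13.0% against 15%. The genome-wide CHG difference was 10.5 points ± 0.977 (SD over 5 chromosomes), and 120 of 121 windows of 1 Mb were on the same side. The widest gap, 18.8 points, was in the 15th Mb of chromosome 1, at 65.7% against 46.9%. Genome-wide CG was 3.92 points ± 1.85 higher and CHH differed by -0.491 points ± 0.187, and between medians over cytosines these differences were 9.09 and -3.57 points. Levels of exactly 100% made up 13.5% of listed CHG cytosines in the library labelled csn8 and 2.41% in that labelled Ws. Levels of 0 made up 40.2% and 36.7%, so the library labelled csn8 had more cytosines at both ends.

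**Figure D4:**
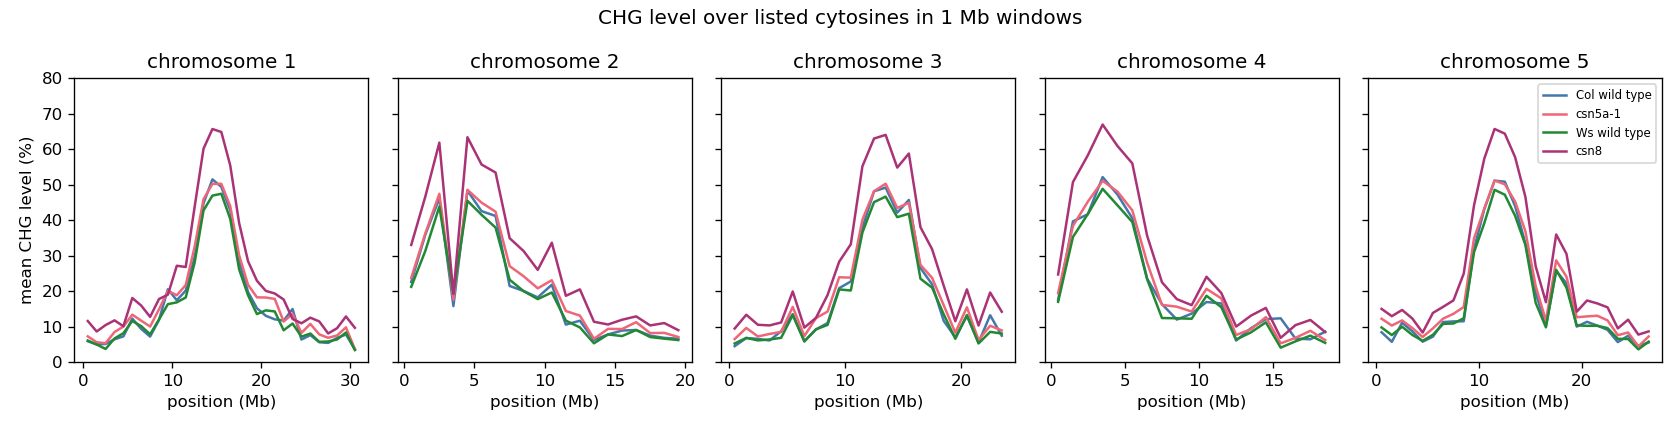
Mean CHG level in percent over listed cytosines in 1 Mb windows along the 5 chromosomes (horizontal axis, position in Mb), 1 line per library. The csn8 line lies above the Ws line in 120 of 121 windows, by up to 18.8 points, and the dip near 3 Mb on chromosome 2 is the dense block of low-level cytosines.

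In CHG, 4796 of 17692 genes were at least 10 points higher in the library labelled csn8 and 402 at least 10 points lower. In CG, 3083 of 16054 were at least 20 points higher and 1954 lower, and in CHH 2536 of 29946 were at least 5 points higher and 2278 lower. Estimated from each strand separately, the CG differences had an SD of error of 5.87 points. The sign was the same on both strands in 4842 of 4853 genes past 20 points, with the limits given for csn5a-1 minus Col.

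The pseudogene AT1G47520 (chromosome 1, 17443786 to 17446282) and the protein-coding AT3G04210 (chromosome 3, 1107604 to 1107650) were at 100% CG in the library labelled csn8 and 0% in the library labelled Ws over 10 cytosines each, as was AT5G37440 over 8. SADHU4-1, another SADHU pseudogene, was at 98.3% against 0%. AT4G08895 had 97.4% against 0% over 22 cytosines, AT2G06560 98.4% against 1.00% over 18, and AT2G24760 and the non-coding AT1G06353 97.0% and 97.5% against 0%. The library labelled Col was above 60% at AT1G47520, SADHU4-1, AT1G06353 and AT2G24760 and at or below 26.5% at the other 4.

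The largest CG loss was AT5G06043, at 0% in the library labelled csn8 and 100% in the library labelled Ws. ERF1-3 (AT3G26618), a translation release factor gene, had 2.38% against 98.7% over 6 cytosines, and AT3G25460 had 0% against 96.4% over 10. AT5G02700 (chromosome 5, 611035 to 611508) was at 0% against 93.9% over 14 cytosines. AT5G22044, AT5G63290, AT5G35796 and AT5G47260 were at 0% in the library labelled csn8 and at 92.3% to 94.2% in the library labelled Ws. In CHG the largest gains were AT1G33102 (95% against 0%), AT3G07395 (89.3% against 0%) and AT4G00891 (90.0% against 1.11%). The largest CHG losses, AT5G06043, AT1G25209 and AT4G10980, were at 0% against 83.9%, 75.0% and 74.7%. In CHH, AT5G36720 had 67.6% against 0%, AT2G08070 57.2% against 0% and LCR31 (AT1G28335) 54.2% against 1.05%, while AT3G33085 had 3.57% against 57.1%, AT1G09557 0% against 48.0% and MIR4245 36.0% against 81.3%.

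Of 24 genes of DNA methylation and demethylation, 8 were at least 20 points higher in CG in the library labelled csn8 and 1 lower, where 31.4% of all measured genes passed the rule in either direction. MET1, the maintenance methyltransferase gene for CG, had 75.3% against 0.272% over 28 cytosines (chromosome 5, 19932341 to 19938011), and DRM2, a de novo methyltransferase gene, 84.7% against 0% over 9. NRPE1, a subunit gene of RNA polymerase V, had 76.7% against 46.2%, RDR2 83.7% against 51.3% and IBM1 69.1% against 22.8%. DML2 was lower, at 2.5% against 26.3%. In CHG, DML3 had 38.4% against 0.857% over 16 cytosines. The list's median was 11.7 points in CG, at percentile 88.8. In methyl donor supply, 3 of 10 were higher, among them MTHFR1 (72.3% against 0%), and MS1 was lower (1.98% against 70.5%), with a list median of 6.87 points at percentile 54.3.

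Of 8 known methylation-sensitive loci, 3 were at least 20 points higher in CG and none lower. QQS, an orphan gene with natural epigenetic variants, had 93.6% against 0% over 14 cytosines (chromosome 3, 12349352 to 12349577), with CHG at 56.0% against 0.245%. FWA, a gene whose loss of promoter methylation delays flowering, had 60.3% against 0.855% over 9, and IBM1 was the other. The FWA value is a mean between the annotated gene ends, and its promoter was not measured separately. FWA CHG was 13.3% in Col, 14.5% in csn5a-1, 11.6% in Ws and 22.2% in csn8. FWA CHH was 13.5%, 9.50%, 7.60% and 8.07% in the same order. The list's median of 14.7 points lay at percentile 98.6. Over the 5 members with at least 10 cytosines it was 17.8 points at percentile 95.1. Against the library labelled Col in place of Ws, it was 9.33 points at percentile 78.4. EVD, a copia retrotransposon, had CHG at 49.2% against 28.8% and CHH at 12.6% against 18.6%. PAI1, PAI2 and PAI3 were at 82.6%, 91.6% and 92.6% in CG against 40.6%, 16.1% and 0.481%. The median of PAI and HISN6 genes was 42.1 points at percentile 98.9, and at 99.4 with at least 10 cytosines per gene. Against the library labelled Col it was 65.5 points at percentile 99.96, although the copies are not 5 independent values.

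Among 11 cullin-RING ligase and neddylation genes, 5 were higher in CG in the library labelled csn8 and none lower. RUB2, encoding a NEDD8/RUB protein, had 58.3% against 0%, CUL3A 57.2% against 14%, TIR1 66.0% against 23.8%, CAND1 85.6% against 59.3% and AXR1 87.3% against 63.2%. The list's median was 16.4 points at percentile 96.0. The percentile was 98.4 for 15 members with no minimum of cytosines and 93.0 for 9 members with at least 10. Against the library labelled Col in place of Ws, the median was 10.7 points at percentile 70.4. In COP9 signalosome genes none of 5 was higher and CSN3 was lower (4% against 24.9%), with a median of 10.8 points at percentile 77.4. Against the library labelled Col this COP9 median was 34.8 points at percentile 99.995. In light signalling PHYA was higher (66.0% against 41.5%) and DET1 lower (14.2% against 40.4%), none of 7 auxin genes passed, and of 4 photosynthesis genes LHCB1.1 was higher (27.8% against 7.26%) and LHCB1.2 lower (0% against 26.1%). Medians of these 3 lists were 7.87, -0.266 and 14.5 points, at percentiles 59.0, 35.5 and 82.3. As the library labelled Ws lacked the PAI methylation known from Ws, these directions are between libraries. They can be neither assigned to the mutation nor denied to it. Against the library labelled Col in place of Ws, 5059 genes passed the CHG rule (4452 higher and 607 lower), and the genome-wide CHG difference was 9.30 points.

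The third comparison, of the wild types, gives the scale between lines as labelled, with the same doubt on the library labelled Ws. QQS had CG at 0% in the library labelled Ws and 83.6% in that labelled Col. The largest gains in the library labelled Ws were AT5G06043 (100% against 1.94%), AT5G03090 (96.3% against 6.61%), the carboxypeptidase-like gene scpl48 (AT3G45010; 89.4% against 0%), AT1G67180 (87.8% against 0%) and the glutathione transferase gene GSTU10 (86.5% against 0%). The largest losses were AT3G05945 (0% against 100%), AT1G42490 (2.83% against 100%), AT2G06225 (0% against 95.8%), AT2G04490 (0% against 94.4%) and AT2G02650 (1.66% against 94.0%). In CG 2580 genes were at least 20 points higher in the library labelled Ws and 1583 lower, a total of 4163 against 4985 for csn5a-1 minus Col and 5037 for csn8 minus Ws. In CHG 710 were higher and 1272 lower, and in CHH 1573 higher and 2732 lower. Genome-wide differences, Ws minus Col, were 2.48 points ± 0.780 in CG, -1.22 ± 0.553 in CHG and -0.677 ± 0.173 in CHH (SD over 5 chromosomes). Between medians over cytosines the CG difference was 8.77 points, and the CHH difference turned to 3.57 points.

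The last comparison set the mutant differences side by side. Some genes were higher in both mutant libraries than in the wild types of their labels. By the smaller of the differences, the largest shared gain was at a locus on chromosome 1 where MRD1 (AT1G53480) and the non-coding AT1G07887 share the same 16 listed CG cytosines (19963194 to 19963701). These were at 93.2% in the library labelled csn5a-1 and 85.9% in the library labelled csn8, against 3.65% in the library labelled Col and 1.46% in the library labelled Ws. The adjoining HEI10 (AT1G53490), a meiotic crossover gene that shares part of these cytosines, had 87.2% and 91.7% against 26.8% and 25.9%. AT1G52630 was at 80.8% and 100% against 0% and 5.04% over 6 cytosines, and the non-coding AT5G06765 at 74.3% and 83.3% against 6.94% and 0%. The largest shared losses were AT5G47300 (32.7% in csn5a-1 and 0% in csn8, against 81.9% in Col and 74.9% in Ws), GLB1 (AT4G01900; 1.39% and 0% against 62.5% and 41.5%), AT5G43155 (1.79% and 0% against 46.5% and 46.2%), AT5G28310 (3.33% and 4% against 47.9% and 45.8%) and GRF9 (AT2G42590; 5.16% and 0% against 42.5% and 61.2%).

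In CG 373 genes were at least 20 points higher in both comparisons, where independent lists of these sizes give 697.1, and 50 were lower in both, where they give 165. By contrast 1107 genes were higher in csn5a-1 minus Col and lower in csn8 minus Ws, where independent lists give 442, and 570 were lower and then higher, where they give 260.2. Across 16054 genes the differences correlated at -0.379 (Pearson) and -0.319 (Spearman). With the wild types exchanged, as csn5a-1 minus Ws and csn8 minus Col, the Pearson correlation was -0.00497, with 330 genes higher in both against 321 for independent lists. In CHG 625 genes were higher in both comparisons against 359 for independent lists, and 13 lower in both against 21.1. In opposite directions, 231 were higher and then lower against 30.1, and 459 lower and then higher against 252. The CHG correlation was -0.185. In CHH 231 were higher in both against 182 and 442 lower in both against 245, while 461 were higher and then lower against 164 and 544 lower and then higher against 273, at a correlation of -0.115. With the wild types exchanged the CHG and CHH correlations were 0.143 and 0.0597. Genes higher in both then numbered 677 in CHG against 313 for independent lists, and 229 in CHH against 136. In CHH every combination of directions exceeded independent lists, before and after the exchange. An excess over independent lists in CHH therefore does not by itself show a shared direction. As the libraries labelled csn5a-1 and Ws resembled each other (r = 0.916), these values do not compare the mutations.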

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

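Gene lists whose median lay on opposite sides of 0 in the mutant comparisons, by at least 1 point each, are given here; the difference between the comparisons was not tested, and all rest on 1 library per group. Medians, csn8 minus Ws, are given first and those of csn5a-1 minus Col second. The libraries labelled csn5a-1 and Ws were the most alike pair across genes in CG (r = 0.916), CHG (r = 0.959) and CHH (r = 0.757). This favours opposite signs of these comparisons. In CG, known methylation-sensitive loci had 14.7 against -12.1 points, with QQS and IBM1 past 20 points in opposite directions. With the wild types exchanged, the medians of this list were 9.33 points for csn8 minus Col and 1.68 for csn5a-1 minus Ws, not of opposite sign. PAI and HISN6 genes had 42.1 against -2.34 points in CG, where the mean of csn5a-1 minus Col was 0.450 points and so not of opposite sign, and 63.1 against -4.05 points in CHG. Auxin genes had a CHG median of 3.24 against -2.02 points. In CHH, light signalling genes had -1.40 against 1.14 points, and photosynthesis and pigment genes -2.62 against 2.5 points. With the wild types exchanged, none of these lists kept opposite signs by at least 1 point each. For csn8 minus Col and csn5a-1 minus Ws, PAI and HISN6 medians were 65.5 and 4.17 points in CG and 58.5 and -0.247 in CHG. Auxin genes had 3.54 and -0.522 in CHG. In CHH, light signalling genes had -0.0515 and -0.177, and photosynthesis and pigment genes -1.39 and -1.41. In this last list the mean of csn5a-1 minus Col was 0.219 points, with 1 of 9 genes at least 5 points higher and 1 lower.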

How the results depend on the processing

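Moved here means by more than the SD over 5 chromosomes, or for counts by more than 1.5 times; the exchange of wild types, the omission of the chromosome 2 block and the choice of CHG cytosines were chosen after seeing the data, the last before its own value was seen. Coverage minimums of 10 and 4 reads were not run, because the levels carry no depth, which also leaves the precision of single levels open. Use of cytosines or genes with values in all 4 libraries is identical by construction, as is the correlation after centring. Leaving out the block moved no level or difference by this measure, and centring no count by over 1.5 times. The SD over chromosomes holds chromosome 2 with the block, the lowest in CG in every library, so it is a wide measure here. Without the block CG levels rose from 41.3% to 43.5% in Col and from 48.4% to 50.7% in csn5a-1. In Ws they rose from 43.7% to 45.5% and in csn8 from 47.7% to 50.3%. Of 198 values of named genes, centring kept the sign of all and moved 8. The cause of the moves was not tested, except that size rules and minimums change counts by construction. No paired analysis was possible because each group has 1 library.

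With medians over cytosines, levels were 25 (Col), 33.8 (Ws) and 42.9 (csn8) in CG, 10 (Col), 12.5 (csn5a-1), 9.09 (Ws) and 23.1 (csn8) in CHG, and 0 (Col, csn5a-1, csn8) and 3.57 (Ws) in CHH, in percent. Median differences were 25 points in CG for csn5a-1 minus Col, 9.09 for csn8 minus Ws and 8.77 for Ws minus Col; 2.5 and 14 in CHG for the mutants; and 0, -3.57 and 3.57 in CHH, the last with its sign reversed.

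With the wild types exchanged, differences for csn5a-1 and csn8 were 4.62 and 6.40 points in CG, 2.57 and 9.30 in CHG and -0.527 and -1.17 in CHH. Correlations of the mutant differences were -0.00497 in CG, and 0.143 in CHG and 0.0597 in CHH with reversed sign. Genes past the rule for csn5a-1 numbered 1921 (CG), 1455 (CHG) and 3134 (CHH). Over CHG cytosines above 0 in Col and csn5a-1, csn8 minus Ws was 15.2 points.

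With at least 10 cytosines per gene, CG counts for csn5a-1 minus Col, csn8 minus Ws and Ws minus Col were 3193, 3159 and 2601, against 4985, 5037 and 4163. CHG counts were 1322 for csn5a-1 and 1200 for the wild types, shared genes 253 (CG) and 412 (CHG), and lists outside percentiles 2.5 to 97.5 in CG 1 (PAI and HISN6 genes in csn8 minus Ws), against 3. With no minimum, CHG counts were 5224, 8377 and 4171, shared CHG genes 1001 and the CHG correlation -0.115.

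With the size rule halved, counts were 8584, 8728 and 7736 in CG, 5380, 8791 and 4718 in CHG and 12811, 12566 and 11219 in CHH, with 1787, 1624 and 2971 shared. At 1.5 times the rule they were 2861, 2867 and 2124, then 1332, 3462 and 1080, then 2663, 2305 and 2044, with 99, 285 and 204 shared. With means in place of medians, CG of PAI and HISN6 genes in csn5a-1 minus Col reversed to 0.450 points, and that of auxin genes in csn8 minus Ws to 0.475.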

Other observations

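Several genes differed alike in the libraries labelled csn5a-1 and Ws against those labelled Col and csn8, or in csn8 alone. The CG level of MS1 was 62.0% and 70.5% in the former pair and 0.231% and 1.98% in the latter. MET1 (75.3%), DRM2 (84.7%), FWA (60.3%) and MTHFR1 (72.3%) were at or below 12.3% in CG in every library except csn8. Of 121 windows of 1 Mb, 35 had CG states in the library labelled csn8 closer to Col than to Ws by at least 5 points, and 3 had states closer to Ws by as much. In all 121 the libraries labelled csn5a-1 and Ws were closer to each other than csn8 was to either wild type.

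For the patterns that follow, all tests were chosen after seeing the data, and that of CHG cytosines above 0 in Col and csn5a-1 was set before its own value was seen. The first pattern is the CG pattern shared by the libraries labelled csn5a-1 and Ws. A swap of labels was taken to need the libraries labelled Col and csn8 to be equally alike, and their correlation across genes was 0.728. As gene-body CG differs between lines, this value alone cannot decide it. Mean PAI CHG was 2.61% in the library labelled Col and 72.0% in that labelled csn8. A swap of the wild types would need it high in the library labelled Col. A swap of the mutants would need it low in the library labelled csn8. Wassilewskija DNA in the library labelled Ws needs PAI methylation, and mean PAI CHG was 0.447%. An effect of the csn5a-1 mutation alone was not separately tested, because the 82.4% of its CG states differing from Col that matched the library labelled Ws follows from the differences between pairs of libraries, as does the 44.5% of csn8 states differing from Ws that matched Col. It stays open also that the library labelled Ws may hold DNA of a Columbia line close to the one behind csn5a-1, with a single wrong label or seed lot, and sequence variants that could decide it were not analysed here.

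The second pattern is the higher CHG level of the library labelled csn8. Incomplete conversion is argued against by its CHG level of 0.196% in the chromosome 2 block. Listing of cytosines because of csn8 itself is argued against as the whole cause by cytosines above 0 in both Col and csn5a-1. Over these, the level was 65.1% in csn8 and 49.9% in Ws, a difference of 15.2 points. They are more methylated than all listed CHG cytosines (35.4% in csn8 and 24.9% in Ws), so the differences in points are not on the same footing. A part played by listing is not excluded. A difference of ecotype or seed lot cannot be told apart from the mutation. Mean PAI CHG was 72.0% in csn8 and under 3% in each other library, so no wild-type library here was shown to share its background. An effect of the csn8 mutation on CHG methylation remains a hypothesis that these libraries leave untested, and so does uneven depth, as coverage is unknown.

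The third pattern is the chromosome 2 block, methylated in the Ws and csn5a-1 libraries and near 0 in Col and csn8. Incomplete conversion, which acts alike on all contexts, is argued against as the whole cause by a CG to CHH ratio of 4.68 in the library labelled Ws. The ratio was 4.88 in that labelled csn5a-1. A part up to the CHH level of the block, 2.58% in the library labelled Ws and 1.15% in that labelled csn5a-1, is not excluded. A larger share of reads from mitochondrial DNA in the libraries labelled Col and csn8 cannot be told apart from a lower level, since depth is unknown. Dilution by unmethylated reads alone was taken to keep the CG to CHH ratio above 2, and neither library had that, at 1.41 in Col and 0.899 in csn8, but unconverted cytosines, which count more at such low levels, were not measured. No biological explanation was tested.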
